A study of Mus musculus with 2 samples.

How the data were processed

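The deposited files hold gene and transcript estimates for 2 total RNA-seq libraries from mouse cells labelled megakaryocyte, 1 file of each kind per replicate. Per the deposited read-me files, values were derived from alignments to the transcriptome of mouse build mm10 with the GENCODE M4 annotation, and replicates were not pooled. The aligner, the quantifier, their versions and the strand setting are not given in the sources used here. Per the labels, fragments ranged from 153 to 499 nt in replicate 1 and from 151 to 499 nt in replicate 2. Without a stated strand, reads of antisense or overlapping genes cannot be told apart, and the antisense genes named are uncertain.

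Expected counts, which need not be whole, are the authors' deposited estimates of reads per gene, in columns named as RSEM writes them. TPM and FPKM values were deposited by the authors as length-normalized levels, TPM also as a posterior mean. Transcript shares in percent were deposited by the authors and were recomputed here from TPM. The bounds of the authors' deposited TPM interval, a signal of unstated confidence level, were not used. Lengths and effective lengths (other values) are those deposited by the authors. TPM depends on the effective length that the quantifier assigned, so short genes such as mt-Atp8 take high TPM for their counts, and TPM is relative to all RNA, including ribosomal RNA.

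The files hold 69691 gene entries, of which 43346 carry an Ensembl ID, 97 are spike-ins and 26248 have number names. Gene names and coordinates came from GENCODE M21 (GRCm38), matched by Ensembl ID without its version: 42462 IDs matched, and the 884 that did not held 0.111% and 0.115% of counts. The gene Ahsp of the erythroid list was not analysed here. Before the data were examined, the design, the alternatives, 25 gene lists and the rule for named genes were fixed. The rule names the 20 nuclear protein-coding genes with the highest mean TPM, in each list the 4 highest members and the lowest, members of other cell types' lists at 50 TPM or more in both libraries, the Y-linked genes, Xist and embryonic globins, the 10 genes called with the largest log2 ratio in each direction, the 6 highest noncoding genes with an effective length of 200 or more, and among isoforms the 5 highest genes and those whose top transcript differed. The low markers Ppbp, Gp1ba, Gp1bb, Gp9, Gp5, Pf4 and Itga2b, and the erythroid gene Car1, were named after their values were seen. A few genes that the rule selects are left out of the text, and remain in the list values.

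A gene was detected at 1 TPM or more in both libraries. The level of a list was the percentile of its median TPM among 10000 random lists of the same size from 21461 nuclear protein-coding genes, and it was called when outside the central 95% in both libraries. List differences used 10000 random lists matched in 20 bins of mean TPM. A gene was called different between libraries when its log2 ratio of TPM + 1 reached 1 in size and the exact 95% binomial interval of its count ratio, from rounded expected counts, excluded equality; genes needed a mean expected count of 50. Reads were called shared where the authors' posterior SD of the count was 10% or more of its mean, a rule set after the data were seen. Intervals and the limit of 3 counts for a gene without counts cover counting error only, since no molecular identifiers are stated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 (TMM factors) and DESeq2 1.42.0 (size factors) were used, the last 2 for alternative scalings alone.

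The steps were tested on simulated data. For genes differing between replicates, over 12229 genes, 0% of 1.5-fold, 10% of 2-fold, 84% of 4-fold and 92% of 8-fold changes were recovered, and 0 of 12029 unchanged genes were called; a 2-fold change lies at the threshold, and adding 1 to TPM lowers its ratio. Counts in that simulation carried Poisson noise alone. The deposited libraries differed by more (chi-square per degree of freedom 31.9), so these rates need not hold for them. For list levels, over 21461 genes, 5 of 200 unchanged lists and 170 of 200 lists raised to 8 times their TPM plus 8 were called. For list differences, over 10913 genes, 6 of 100 unchanged lists and 100 of 100 lists shifted by 0.5 were called. Alternatives changed the detection limit, pseudocount, count minimum, scaling, background, unit and size threshold, and left out each replicate in turn.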

Results

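Total RNA was sequenced from primary mouse cells labelled megakaryocyte, the large marrow cells that shed platelets, from adult male C57BL/6J mice aged 5 to 6 weeks. Both libraries were made from 1 ng of RNA and are called replicates 1 and 2. The labels give 1 group of 2 biological replicates and 1 donor identifier for both, so no condition could be compared and separate animals are not stated. Expected counts summed to 75862868 in replicate 1 and 65434777 in replicate 2. At 1 TPM or more, 11083 genes were detected in both libraries, 9887 of them nuclear protein-coding genes. Levels below are mean ± SD (n = 2) in TPM, the level normalized for length and depth, unless both library values are given. Because the marker genes described below went against the cell type in the labels, the samples are called the libraries labelled megakaryocyte.

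The most abundant nuclear protein-coding genes in the libraries labelled megakaryocyte included 7 genes of the neutrophil and monocyte lists, among them the 3 highest. S100a9 and S100a8, the subunits of the calcium-binding protein calprotectin of neutrophils and monocytes, stood at 13353 ± 2335 and 11527 ± 1794 TPM. Lyz2, which encodes lysozyme of myeloid cells, reached 12436 ± 1067 TPM, the monocyte surface gene Ly6c2 4468 ± 118 TPM, and the neutrophil granule genes Ngp and Lcn2 4302 ± 792 and 1856 ± 318 TPM. Retnlg, another neutrophil gene, stood at 1948 ± 215 TPM. These genes lie, in GRCm38 coordinates, at chromosome 3, 90692632 to 90695721 (S100a9), chromosome 3, 90668978 to 90670035 (S100a8), chromosome 10, 117277331 to 117282321 (Lyz2), chromosome 15, 75108158 to 75111970 (Ly6c2) and chromosome 9, 110419747 to 110423012 (Ngp). The other genes among the 20 most abundant are expressed in most cells or in many blood cells: Eef1a1 (5480.1 ± 398 TPM), Tmsb4x (5135 ± 200.5), Actb (4693 ± 121), Tpt1 (2579 ± 179), B2m (2499 ± 77.2), Actg1 (1970.1 ± 135), Tmsb10 (1799.8 ± 33.5), H3f3a (1657 ± 165), Ppia (1647 ± 102), Arhgdib (1562 ± 61.9), Ptma (1502 ± 149), Ly6e (1497 ± 21.3) and S100a11 (1492 ± 121). Together the 20 genes held 8.34% ± 0.275 of all TPM. That share was 17.6% once Gm42418 and mitochondrial, ribosomal RNA, spike-in and short entries were left out, with all 20 genes retained. It was 5.61% in CPM, where 10 of the 20 genes were shared.

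Most genes that define megakaryocytes and platelets were below 1 TPM in at least 1 library. Pf4, the platelet chemokine, was at 1.92 and 0.33 TPM in replicates 1 and 2, from 47 and 7 expected counts (exact Poisson 95% intervals 34.5 to 62.5 and 2.81 to 14.4). Ppbp was at 0.25 and 0.29 TPM, and the von Willebrand receptor genes Gp1ba, Gp1bb, Gp9 and Gp5 at 0.39 and 0.18 TPM, 0.23 and 0.56 TPM, 0.080 and 1.02 TPM and 0.17 and 0.030 TPM. Tubb1, the platelet tubulin, Gp6 and Mmrn1 had no counts, which allows up to 0.0433 and 0.0496 TPM of Tubb1 at a limit of 3 counts. Itga2b, the integrin chain CD41, was at 6.55 ± 0.962 TPM. The 4 highest members of this list were Plek (54.4 ± 2.52 TPM), Rgs18 (49.1 ± 3.76), Cd9 (46.5 ± 1.12) and Thbs1 (12.6 ± 0.665), genes that many blood cells express. The median of the 22 markers was 0.24 and 0.59 TPM in replicates 1 and 2 (0.412 ± 0.244), and 7 markers reached 1 TPM in both libraries. Among random lists of protein-coding genes this was neither high nor low (percentiles 33 and 46.8), of which 10419 of 21461 genes reached 1 TPM in either library. Among random lists of genes at 1 TPM or more it lay at percentiles 0 and 0, below the central 95% in both libraries. A list median below 1 TPM comes out low there by construction, so this call adds nothing to the median itself.

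The question set by the label is how far megakaryocyte markers stood above those of other marrow cells. They stood below 7 of the 9 other cell types in both libraries. The difference of median log2(TPM + 1), megakaryocyte minus other, was -7.01 ± 0.26 for neutrophils and granulocyte precursors, -2.81 ± 0.20 for dendritic cells, -2.75 ± 0.10 for mast cells, basophils and eosinophils, and -2.60 ± 0.11 for monocytes and macrophages (mean ± SD, n = 2). It was -1.59 ± 0.44 for erythroid cells, -1.09 ± 0.08 for T and natural killer cells and -0.92 ± 0.42 for stem and progenitor cells. The marker list stood above the B lineage list by 0.29 ± 0.05 and above the stromal and endothelial list by 0.19 ± 0.23, the latter less than its SD, and in CPM the stromal difference was -0.12. The sizes depended on the setting. From a pseudocount of 0.1 to one of 5 the difference went from -8.54 to -5.09 for neutrophils, -4.21 to -1.36 for dendritic cells, -4.15 to -1.32 for mast cells, basophils and eosinophils, -3.97 to -1.21 for monocytes, -2.75 to -0.62 for erythroid cells, -2.11 to -0.37 for T and natural killer cells, -1.85 to -0.30 for stem cells, 1.13 to 0.07 for the B lineage and 0.55 to 0.05 for stromal cells. By mean log2(TPM + 1) it was -0.27 for T and natural killer cells, 0.83 for the B lineage and 0.79 for stromal cells, in CPM -1.71 for stem cells and 0.20 for the B lineage, and without replicates 1 and 2 0.35 and 0.02 for stromal cells. Without the 4 markers that many blood cells express, a setting chosen after seeing the data, it was 0.11 for the B lineage and 0.01 for stromal cells. No p-value is given, since 2 paired differences cannot go below an exact two-sided permutation p, by exchange of signs, of 0.50.

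**Figure D1:**
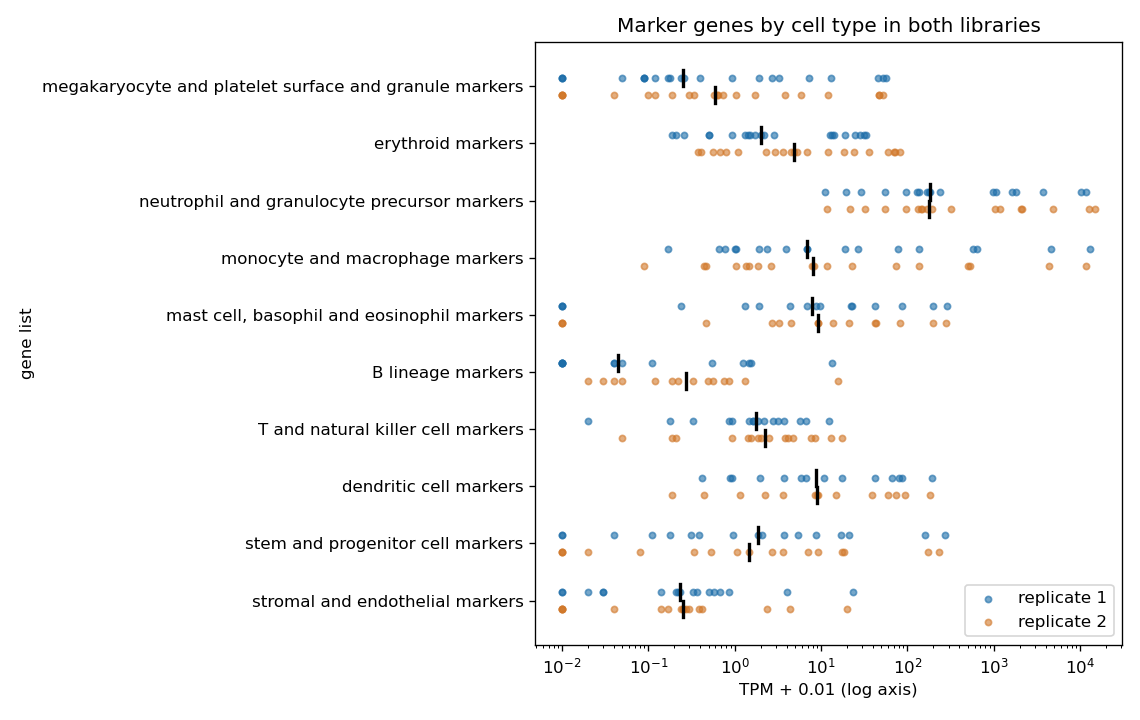
Each point is 1 gene of a marker list in 1 library (TPM plus 0.01, log axis), blue for replicate 1 and orange for replicate 2, and black bars are list medians. The median of the megakaryocyte list lies at 0.24 and 0.59 TPM and that of the neutrophil list at 181 and 179 TPM.

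Granulocyte genes were high as a group. All 18 members of the neutrophil and granulocyte precursor list reached 10 TPM in both libraries, with a median of 181 and 179 TPM and percentiles 100 and 100 among random lists of protein-coding genes. Beside the genes already named, Camp and Chil3 stood at 1075 ± 144 and 1045 ± 9.5 TPM, and the secondary granule genes Ltf and Mmp8 at 278 ± 54.3 and 186 ± 6.87 TPM. The primary granule genes Elane, Prtn3, Mpo and Ctsg, made by granulocyte precursors, were at 174 ± 8.92, 156 ± 18, 138 ± 12.8 and 134 ± 3.47 TPM. Csf3r, the receptor of granulocyte colony-stimulating factor, was at 96.2 ± 1.32 TPM and Fcnb at 55.1 ± 0.0636 TPM, and the lowest member was the transcription factor gene Cebpe at 11.4 ± 0.332 TPM.

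Several other cell types had some abundant markers and many low ones. Among monocyte and macrophage genes, Ctss, Ccr2, Cd68 and Csf1r followed Lyz2 and Ly6c2 at 587 ± 78.4, 543 ± 55.6, 136 ± 1.24 and 75.8 ± 2.01 TPM, while Spic, a gene of red pulp macrophages, was at 0.12 ± 0.0566 TPM; the list median was 6.91 and 8.09 TPM (percentiles 95.6 and 97.6). The basophil protease genes Mcpt8 and Prss34 were at 283 ± 8.11 and 198 ± 2.67 TPM, with Cpa3 at 84.8 ± 2.66 and Fcer1a at 42 ± 0.481, and the connective tissue mast cell protease gene Mcpt4 had no counts; that list's median was 7.85 and 9.17 TPM (percentiles 96 and 97.7). Among dendritic cell genes, Cd74, H2-Aa, Irf8 and H2-Ab1 led at 185 ± 6.91, 91.2 ± 5.49, 77.1 ± 3.45 and 63.6 ± 4.99 TPM and Xcr1 was lowest at 0.295 ± 0.163, with a median of 8.8 and 9.09 TPM (percentiles 96.5 and 97.2). In the stem and progenitor list, Cd48 (254 ± 26.8 TPM), Spi1 (165 ± 8.94), Cebpa (19.4 ± 2.5) and Myb (17.7 ± 1.2) led, Slamf1 had no counts, and the median was 1.87 and 1.44 TPM (percentiles 71 and 65.5). None of these 4 lists passed the test in both libraries, but by mean log2(TPM + 1) the monocyte, mast cell and dendritic lists were called high (mean percentiles 100, 99.1 and 99.7). Without replicate 1 the monocyte and mast cell lists were called high (97.6 and 97.7), as was the monocyte list in CPM (97.8). Among genes at 1 TPM or more, the stem and progenitor list was called low (percentiles 0 and 0).

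The lymphoid, stromal and erythroid lists had medians of 4.9 TPM or less in both libraries, and none was called. By mean log2(TPM + 1) the B lineage and stromal lists were called low (mean percentiles 1.15 and 0.935). All of these lists were called low among genes at 1 TPM or more. For the B lineage and stromal lists, with medians below 1 TPM, that background gives the low call by construction. Nkg7, Gzma, Ncr1 and Cd3g led the T and natural killer cell list at 14.9 ± 3.59, 9.93 ± 4.63, 7.05 ± 1.92 and 5.23 ± 3.44 TPM and Cd8a was lowest at 0.105 ± 0.134, with a list median of 1.75 and 2.25 TPM (percentiles 67.1 and 72.7). Cd79b was at 14.5 ± 1.71 TPM, and Blnk, Cd22, Fcrla and Rag1 at 1.43 ± 0.148, 1.05 ± 0.269, 1 ± 0.636 and 0.010 ± 0.0141, for a B lineage median of 0.035 and 0.265 TPM (percentiles 17.3 and 34.3). Of stromal and endothelial genes, Lpl, Cxcl12, Lepr and Bglap were at 21.8 ± 2.26, 4.17 ± 0.247, 1.33 ± 1.43 and 0.54 ± 0.184 TPM and Tek had no counts (median 0.22 and 0.24 TPM, percentiles 37.3 and 36.9). The adult globins Hbb-bs, Hba-a2, Hbb-bt and Hba-a1 led the erythroid list at 56.1 ± 35.4, 51.9 ± 26.5, 50.1 ± 30.8 and 41.9 ± 24.6 TPM, and Tfr2 was lowest at 0.30 ± 0.141 (median 2.01 and 4.9 TPM, percentiles 74.6 and 92.5). Each globin pair is nearly identical in sequence, but the posterior SD was only 3.31% to 3.86% of the count in the authors' estimates; the pair sums were 106 ± 66.2 TPM for Hbb-bt with Hbb-bs and 93.7 ± 51.1 TPM for Hba-a1 with Hba-a2. The embryonic globins Hbb-y, Hbb-bh1 and Hba-x had no counts, with limits at 3 counts of 0.115 and 0.131 TPM for Hbb-bh1. Their list lay at percentiles 15.7 and 15.8. It was called low by mean log2(TPM + 1) (mean percentile 2.37) and, by construction, among genes at 1 TPM or more (mean percentile 0). The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were at 49.3 ± 8.52, 14 ± 0.191, 7.51 ± 2.12 and 5.86 ± 0.17 TPM and Xist, the RNA of the inactive X chromosome, had no counts, in mice labelled male (list median 6.01 and 9.01 TPM, percentiles 79.8 and 87.4).

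Of the other lists of megakaryocyte function, 4 were high. The cytoskeleton list had a median of 115 and 126 TPM (percentiles 100 and 100), led by Tmsb4x and Actb with Cfl1 and Pfn1 at 1007 ± 12.1 and 834 ± 46.7 TPM, while Tubb1 had no counts. The signalling list had a median of 31 and 31.1 TPM (percentiles 100 and 100), with Gnai2, Rap1b, Lyn and Fyb at 341 ± 11.2, 282 ± 31.3, 129 ± 1.7 and 104 ± 5.36 TPM and Src at 0.025 ± 0.0354. Transcription factor genes had a median of 10.6 and 10.1 TPM (percentiles 98.8 and 98.8), with Nfe2, Lmo2, Runx1 and Fli1 at 104 ± 15.4, 86.8 ± 3.15, 45.1 ± 6.19 and 40.9 ± 1.79 TPM and Tal1 at 1.34 ± 0.509. The thrombopoietin signalling list stood at 9.9 and 9.53 TPM (percentiles 97.9 and 98), with Cbl, Grb2, Sh2b3 and Jak2 at 56.6 ± 1.52, 49.1 ± 0.742, 37.6 ± 0.233 and 34.7 ± 2.14 TPM. These 4 lists were called high among random lists of protein-coding genes; among genes at 1 TPM or more, the transcription factor and thrombopoietin lists moved to mean percentiles 42.3 and 37.2. The alpha granule list (6.11 and 5.19 TPM, percentiles 95.4 and 93.6) was led by F13a1, Srgn, Tgfb1 and Vamp8 at 382 ± 6.3, 296 ± 1.95, 125 ± 4.28 and 102 ± 3.89 TPM, with Mmrn1 at 0 counts. The dense granule list (8.48 and 7.33 TPM, percentiles 97.8 and 96.9) was led by Rab32, Hps3, Lyst and Rab27a at 75.4 ± 7.74, 49.6 ± 1.65, 44.6 ± 1.62 and 25.7 ± 1.43 TPM, and Slc35d3 had no counts. Fcer1g, Itgb1, Cd63 and P2ry1 led the platelet receptor list at 917 ± 16.4, 41 ± 2.77, 36.1 ± 5.08 and 12.1 ± 2.12 TPM and Adra2a had no counts (1.18 and 1.71 TPM, percentiles 64.8 and 72.2). The last 3 lists were not called, but by mean log2(TPM + 1) the alpha and dense granule lists were called high (mean percentiles 98.9 and 99.7), and the dense granule list also without replicate 2 (97.8) and in CPM (98.6). Among genes at 1 TPM or more, the platelet receptor list was called low (percentiles 0 and 0).

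Cell cycle genes were high: all 32 members reached 1 TPM in both libraries, with a median of 30.5 and 28.9 TPM (percentiles 100 and 100). Mki67, a marker of cycling cells, was at 245 ± 6.27 TPM, Mcm3, Ccnd3 and Top2a at 153 ± 12.5, 143 ± 0.559 and 137 ± 1.27, and Ccnd2 was lowest at 2.34 ± 0.679. Among immediate early genes, Zfp36, Fos, Dusp1 and Jun were at 228 ± 4.35, 212 ± 5.11, 105 ± 4.54 and 40.5 ± 0.403 TPM and Hspa1a at 5.2 ± 0.424 (list median 20.4 and 15.5 TPM, percentiles 99.9 and 99.7). Interferon response genes included Ifitm3, Zbp1 and Oasl2 at 944 ± 49.6, 26.4 ± 2.27 and 22.5 ± 1.99 TPM, with Ifi44 at 0.395 ± 0.318 (11.3 and 10.7 TPM, percentiles 98.8 and 98.7). Ribosomal protein genes had a median of 679 and 653 TPM (percentiles 100 and 100), led by Rps12, Rps24, Rps27 and Rpl10 at 1483 ± 6.0, 1478 ± 26, 1369.5 ± 63.2 and 1368 ± 126 TPM, with Rpl36-ps4 at 0 counts. Histone genes, of which 10 of 65 had a posterior SD of 10% or more of the count, had a median of 36.5 and 27.9 TPM (percentiles 100 and 100), with Hist1h4d, Hist2h3b, Hist1h1e and Hist1h1b at 1165 ± 45.6, 580.5 ± 198, 576 ± 50.1 and 359 ± 2.1 TPM and Hist1h2ad at 0 counts. The median over mitochondrially encoded genes was 0 (percentiles 2.95 and 2.87), and 22 of the 37, such as mt-Tc, had no counts. The list was called low by posterior mean TPM (mean percentile 0). It was low by construction, with a median of 0, among genes at 1 TPM or more (mean percentile 0). By mean log2(TPM + 1) it was called high (100), and 15 members reached 10 TPM or more in both libraries. The highest members were mt-Rnr1 and mt-Rnr2, followed by mt-Atp8 (14022 ± 1178 TPM) and mt-Co1 (11848 ± 113 TPM). In the 5 calls above, the immediate early and interferon lists were no longer called among genes at 1 TPM or more, at mean percentiles 87 and 49.5, and the interferon list was not called in CPM (96).

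Mitochondrial RNA and the gene Gm42418 took much of both libraries. The long noncoding RNA gene Gm42418 (chromosome 17, 39846958 to 39848788) alone held 23.6% and 25.6% of expected counts, at 200559 ± 10301 TPM. The RefSeq ribosomal RNA pseudogene Rn18s-rs5 overlaps 68% of it. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were at 117830 ± 1988 and 117633 ± 6532 TPM. Among the 6 most abundant noncoding genes, the others were Malat1 (615 ± 16.4 TPM), Gm42743 (613 ± 104) and Gm26917 (456 ± 66.6), the last beside Gm42418 on chromosome 17. By class, nuclear protein-coding genes held 44.1% ± 0.701 of TPM, mitochondrial ribosomal RNAs 23.5% ± 0.454, Gm42418 20.1% ± 1.03, other mitochondrial genes 6.18% ± 0.255, pseudogenes 3.37% ± 0.0848, small structured RNAs 1.94% ± 0.256 and other long noncoding RNAs 0.629% ± 0.00378. Nuclear protein-coding genes held 50.4% ± 1.05 of expected counts.

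Between the libraries, erythroid genes differed most among the fixed lists: 17 of 18 members with a mean expected count of 50 or more were higher in replicate 2, with a median log2 ratio of 0.87 (replicate 2 over replicate 1, on log2(TPM + 1)) at percentile 100 of random lists matched on expression. Hbb-bs and Hbb-bt were at 31.1 and 81.1 TPM and 28.3 and 72 TPM, and Car1 (carbonic anhydrase 1) at 18.8 and 35.8 TPM. T and natural killer cell genes had a median of 0.39 (percentile 99.99, 11 of 14 higher), with Gzma at 6.65 and 13.2 TPM and Cd3g at 2.8 and 7.66 TPM. Neutrophil genes had a median of 0.15 (percentile 100, 12 of 18 higher), with S100a9 at 11701 and 15004 TPM and Ltf at 240 and 317 TPM. Monocyte genes had a median of -0.18 (percentile 1.48), 4 of 15 higher, and the call ended with pseudocounts of 0.1 and 5 (percentiles 2.83 and 4.79). Histones had -0.12 (percentile 1.6), a call that ended with counts scaled by TMM (percentile 3.42) or lists matched on length (percentile 5.08). These 5 of 24 lists lay outside the central 95% of random lists, where chance gives 1.2. The megakaryocyte marker list had a median of -0.13 (percentile 18). Platelet receptor genes had 0.05, but were called higher with counts scaled by TMM (percentile 99.9), and interferon genes -0.17, called lower with a pseudocount of 5 (percentile 2.23). The lists not called lay at medians from -0.20 to 0.06, and the embryonic globin list had too few counts to test. These values compare 2 libraries, not conditions.

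**Figure D2:**
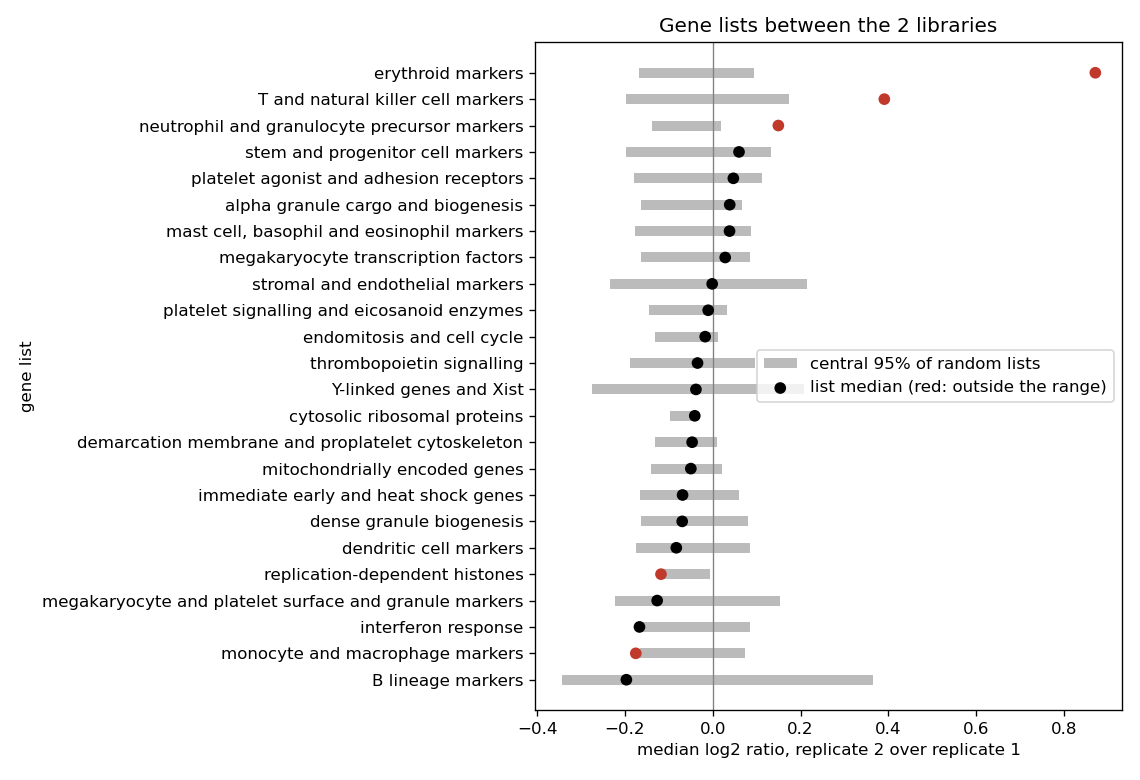
Points are the median log2 ratio of each gene list, replicate 2 over replicate 1, and grey bars the central 95% of 10000 random lists matched on expression. The erythroid list lies at 0.87, with the T and natural killer cell list next at 0.39; red points lie outside the bar.

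Single genes agreed closely otherwise. Across 12229 genes with a mean expected count of 50 or more, Pearson's r of log2(TPM + 1) was 0.987 and Spearman's rho 0.983, and 98.8% of genes lay within 2-fold; these describe genes, which are not independent replicates. Counts differed by more than sampling noise (chi-square per degree of freedom 31.9), so the libraries are not 1 library deposited more than once. Of these genes, 77 were called higher and 63 lower in replicate 2 by 2-fold or more on the log2(TPM + 1) scale. The largest log2 ratios were Rpl7a-ps11 (4.83), Gm28438 (4.23), Gm7336 (3.43), mt-Nd4l (2.52), Gm20634 (2.41), Gm15491 (2.36), Gm6750 (2.28), ENSMUSG00000103212.1 (2.03), Igha (1.89) and Kel (1.88) upward, and Hist2h3c1 (-3.38), Hist1h3h (-3.11), ENSMUSG00000102843.1 (-2.97), Gm10800 (-2.89), Gm17344 (-2.65), Gm14410 (-2.19), Gm26870 (-2.18), Gm21738 (-2.03), Gm4724 (-1.92) and Gm14845 (-1.91) downward. Igha encodes the constant region of immunoglobulin A, and Kel a red cell surface protein. Of these 20 genes, 16 had a posterior SD of 10% or more of the count in the authors' estimates, as reads shared with other genes give, and their values are uncertain. The exceptions were Igha, Kel, Gm21738 and Gm10800. Kel rested on 47 and 154 expected counts (count ratio, exact binomial 95% interval 2.72 to 5.38), and its log2 ratio was 1.06 with counts scaled by TMM and 0.82, no longer called, with a pseudocount of 5. Of the 20 genes, 5 lost their call with a pseudocount of 5 and 1, Gm14845, with counts scaled by TMM. Igha had 1124 and 3789 expected counts, a count ratio with an exact binomial 95% interval of 3.66 to 4.18. A posterior SD of 10% or more of the count was found for 35.7% of called genes against 2.03% of all genes tested. With a pseudocount of 0.1, 500 genes were called, and with one of 5, 27. With counts scaled by TMM, 114 were called (74 higher, 40 lower), and only 75 of these were among the main calls.

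Most genes of the megakaryocyte lists had the same most abundant transcript in both libraries. Of 71 genes with 10 TPM or more and several annotated transcripts, 64 (90.1%, exact binomial 95% interval 80.7 to 95.9) did. That interval treats the listed genes as independent, and it measures no spread over animals or libraries. The leading transcript held 56.6% ± 4.24 of the gene's TPM in Tmsb4x, 98.9% ± 0.133 in Actb, 97.7% ± 0.207 in Fcer1g, 98.3% ± 0.0442 in Pfn1 and 98.1% ± 0.264 in Cdc42. Its share could still differ between libraries in genes counted as the same. In replicates 1 and 2 it was 53.8% and 88.5% in Jak2 and 50.5% and 77.6% in Grb2. In Sptan1 it was 49.7% and 24.2%, and in Stat3 75.2% and 52.4%. The leading transcript differed in Stxbp2, Inpp5d, Dnm2, Rab27a, Stat5b, Tpm1 and Pecam1, where it held 25% to 64.2% of the gene's TPM.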

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

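Signals appeared in entries that no comparison used, above the limit of 3 counts. The spike-in entries held 2690 expected counts in replicate 1 and 2209 in replicate 2, or 35.5 and 33.8 CPM (exact binomial 95% intervals 34.1 to 36.8 and 32.4 to 35.2). The labels name spike-ins, but the amounts added are not given in the sources used here. Entries with number names held 22 and 38 expected counts.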

How the results depend on the processing

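The setting with genes that share few reads and the marker list without broadly expressed genes were chosen after seeing the data; a first marker list, which left out 4 more genes, was discarded because its genes had been picked on their values. Megakaryocyte markers stood below 7 of 9 cell types in both libraries under all settings except CPM (8), including the list without Rgs18, Plek, Cd9 and Thbs1, whose median was 0.165 and 0.31 TPM. Genes called different went from 140 (77 higher, 63 lower) to 500 (260 higher, 240 lower) with a pseudocount of 0.1, 27 (17 higher, 10 lower) with one of 5, 328 (185 higher, 143 lower) at 10 counts, 48 (25 higher, 23 lower) at 200 counts, 699 (369 higher, 330 lower) at 1.5-fold, 16 (8 higher, 8 lower) at 4-fold, 114 (74 higher, 40 lower) with counts scaled by TMM or DESeq2 size factors, and 90 (53 higher, 37 lower) for genes that share few reads. Fewer or more genes passed by construction of each threshold; for the scalings the cause was not tested, and 75 genes were shared with the main calls. Lists called high went from 10 to 6 against genes at 1 TPM or more and 16 by mean log2(TPM + 1). Lists called low went from 0 to 9, 3 and, by posterior mean TPM, 1. Against genes at 1 TPM or more, a list with a median below 1 TPM is low by construction. Among lists whose call changed against genes at 1 TPM or more, mean percentiles crossed the middle for transcription factors (42.3), thrombopoietin signalling (37.2), interferon response (49.5), erythroid markers (0.695) and platelet receptors, T and natural killer cell and stem cell markers (0 each), because that background leaves out silent genes; 6 lists called in neither setting crossed it too, to between 3.16 and 30.0, as did T and natural killer cell markers by mean log2(TPM + 1) (44.5). The mitochondrial list went to percentile 100 by mean log2(TPM + 1). Of its 37 members, 22 had no counts, which fixes the median at 0, while 15 reached 10 TPM or more in both libraries. The stromal difference went to -0.12 in CPM, and the cause of that was not tested. Of 511 other values, for single genes and lists, 409 kept their call or moved within the SD, 57 moved beyond the SD, 22 gained and 14 lost their call, and 9 changed direction with their call or sign, as given above. Lists higher in replicate 2 went from 3 to 4 with TMM or DESeq2 size factors, the addition being platelet receptors. With a pseudocount of 5 interferon genes replaced monocyte genes among those lower. Lists lower in replicate 2 went from 2 to 1 with a pseudocount of 0.1, TMM, DESeq2 size factors or length matching. Pearson's r moved to 0.978 with a pseudocount of 0.1 and 0.984 at 10 counts; the 20-gene share to 17.6% rescaled and 5.61% in CPM; the protein-coding share to 50.4% of counts; the shared top transcript to 96.8% at 50 TPM. Leaving out each replicate gave 11671 to 11767 detected genes, 8.16% to 8.54% for the 20-gene share, 43.6% to 44.6% for protein-coding genes, and 11 to 12 high lists; agreement of top transcripts and differences between libraries need both. No paired analysis between groups was possible because the labels give 1 group and no other to pair it with. The differences of the megakaryocyte markers from other cell types' markers were taken within each library. Several megakaryocyte genes rest on under 50 counts, so their values are imprecise. Nuclear protein-coding genes held 38828995 and 32519451 expected counts in replicates 1 and 2. At that depth 3 counts of Tubb1 would stand for 0.0433 and 0.0496 TPM, so the low counts went with low TPM. A limit set by depth was not shown.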

Other observations

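Apart from Nr4a1, a member of the immediate early list, these genes are outside the fixed lists. All were chosen after their values were seen and test no cell type. Cx3cr1 was at 41.5 ± 1.7 TPM, Spn at 34.9 ± 2.52, Nr4a1 at 14 ± 3.58, Fcgr4 at 15.6 ± 0.156, Ace at 3.65 ± 0.474 and Treml4 at 2.65 ± 0.205 (mean ± SD, n = 2). Igkc was at 85.4 and 267 TPM, and Jchain, which joins polymeric immunoglobulins, at 6.65 and 25.8 TPM in replicates 1 and 2. Xbp1, expressed in many secretory cells, was at 112 ± 0.488 TPM.

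The tests on megakaryocyte markers, and those on erythroid genes other than the correction for GC content and length, were chosen after the result was seen, as was the test of Gm42418. In the libraries labelled megakaryocyte, marker levels went against the label. A small admixture of other blood cells to megakaryocytes would leave the marker list above the granulocyte list. The marker list minus the granulocyte list gave a median log2 difference of -7.01 ± 0.26 (SD, n = 2). This difference is part of the pattern itself and no separate test, but the pattern as it stands argues against a small admixture. A wrong label, a swap with an outside sample and a preparation with few megakaryocytes stay open: the marker median of 0.412 TPM is part of the pattern itself and does not test them. No biological explanation was tested.

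Erythroid genes were higher in replicate 2. A bias of GC content or length is argued against, since the erythroid median log2 ratio was 0.87 after centring within bins of both, against 0.87 before, and the central 95% of random lists ran from -0.12 to 0.13. A lower share of the main cell type would raise all other types alike. The erythroid median exceeded that of mast cells, basophils and eosinophils by 0.83 (bootstrap 95% interval over genes, 0.34 to 1.02), so these lists did not move alike. The erythroid list was picked as the one that differed most, which favoured a positive value beforehand. The main cell type was not identified either, so this value does not decide the point. More RNA from erythroid cells stays open. The 14 members other than globins had a median of 0.80, with 13 higher in replicate 2, but since 17 of all 18 were higher, at least 13 of these had to be, so the value does not test it. No biological explanation was tested, since the design gives 1 group.

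Gm42418 held 23.6% and 25.6% of the counts. A candidate explanation is that reads of ribosomal RNA were counted there: the RefSeq gene Rn18s-rs5, a pseudogene of 18S ribosomal RNA on GRCm38 (chromosome 17, 39846354 to 39848202), overlaps 68% of Gm42418. The overlap does not show where the reads came from, and no biological explanation was tested.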
